A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

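Small RNA libraries of 2 strains were used, with 2 libraries labelled WT and 2 labelled ABP1d. Per the labels' protocols, total RNA was extracted with acid phenol, adapters were ligated with an Illumina small RNA kit, and amplified products were selected by size before sequencing. Bowtie 0.12.5 is named in the submitters' processing notes. The genome build, read filters, treatment of reads with several matches, region caller, normalization and statistical test are not given in the sources used here. The labels call the libraries strand-specific, but the files carry no strand, so sense and antisense could not be separated.

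The authors deposited 3 region files without headers. As deposited, the authors' RPKM values are reads scaled to region length and to a total, pooled over the libraries of a strain; how the authors chose that total is not given in the sources used here. The list of each strain holds an RPKM value and a p-value per region, and the comparison holds an RPKM value for each strain and a p-value per window. The labels tie each list to its strain. The columns of the comparison were assigned by joining coordinates with the lists: all 7 shared regions matched the ABP1d list in the first value column, all 124 shared regions matched the WT list in the second, and none matched the other way round. No value column was left unmapped. The deposited p-values of the comparison reach 0.0494, and 1095 are listed as 0. Across the 2917 windows with a p above 0, their order followed that of a likelihood ratio test on the pooled reads of the strains (Spearman's rho = 1.00 across windows, which are not independent), so they hold no spread between libraries.

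RPKM times length is a whole multiple of a single step in each strain, and the inverse of that step gave the totals. Reads were whole for 100% of regions, to within 1e-06. The comparison windows alone add up to 99.6% and 99.7% of the totals, and reads of the rRNA repeats, entered at each copy, make up 47.8% of the ABP1d total and 67.0% of the WT total, with 5S genes at 25.2% and 10.7%. Totals are thus close to sums over regions, what they count is not stated, and the depth per library is unknown. Ratios of RPM (reads scaled to the strain's total) have exact 95% binomial intervals conditional on the reads of both strains. Against a count of 0, a floor of 3 reads over the pooled strain was used and the ratio was given as a bound. The design fixed beforehand foresaw a count test if reads per library were given; the files hold pooled RPKM, so no such test was made.

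Coordinates were used on chromosomes I to III of the RefSeq assembly ASM294v3, after a check with A/T runs of at least 15 bases: 169 of 304 ABP1d regions hold one at the listed place and 3 after a shift of 1000 bases. Starts were read as 0-based and are printed 1-based. The mitochondrial, mating-type and telomeric contigs are not in that assembly by name and were used without gene names. Mitochondrial windows formed a class of their own. Windows of the mating-type contig were put in the mating-type locus class (37 of its 42 comparison windows) and those of the telomeric contig in the subtelomere class. Each region took the first class it overlapped by at least 1 base, in the order Tf2 element with LTRs within 500 bases, other LTR, rRNA repeat, 5S rRNA, tRNA, snoRNA, snRNA or other structured ncRNA, centromere, mating-type locus, subtelomere (50 kb at the ends of chromosomes I and II), protein-coding gene, other ncRNA and intergenic. Lists were compared by overlap of at least 1 base, with classes by random placement (10000 placements) and by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. Placement counts every class a region overlaps. For gene lists, reads were summed over a gene's windows without A/T runs; Fisher's exact test over the lists was added after the data were seen.

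Named regions followed a rule fixed before the data were examined: the 10 highest and 10 lowest ratios, the abp1 gene (cbp1 in the annotation) with cbh1 and cbh2, the Tf2 elements, rRNA repeats, centromeric repeats, cenH, tlh1 and tlh2, the longest regions in one strain list only (up to 10 per strain; WT had none), and up to 4 members of each of 10 gene lists with the largest absolute ratio. Other named windows were chosen after their values were seen: the snoRNA, tRNA-Ala and 5S windows, the rRNA spacer window, and the windows picked within centromeres and the mating-type contig.

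The steps were tested on simulated data. On 4012 simulated windows the totals and 100% of reads were recovered and 96.9% of intervals held the simulated ratio. Among 400 placed regions, the class with added regions had a permutation p = 0.001, and 1 class of a random list of 400 had an unadjusted p under 0.05. A first simulated table of directions gave an adjusted call for 1 class that was not changed, so the simulation was repeated; the Fisher test then called the changed class in 100 of 100 tables of 4012 windows, and unchanged classes at a mean of 0.22 per table. Simulated reads and directions were independent between windows, whereas copies of a repeat share reads. The interval coverage and the rate of calls therefore do not carry over to such copies. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives for merging, thresholds, overlap, class assignment, placement and scaling were computed, and their effect is given in the closing section.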

Results

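Small RNA libraries were sequenced from exponentially growing fission yeast (Schizosaccharomyces pombe) in rich medium, with 2 libraries of a wild-type strain (WT) and 2 of a strain labelled ABP1d. Abp1 is a fission yeast homolog of the centromere protein CENP-B, a DNA-binding protein related to transposases, and the series asks about its part in keeping the Tf2 retrotransposons and the rRNA gene repeats silent. The deposited values were a list of small RNA regions for each strain and a table of windows that differed between the strains, with 1 pooled RPKM value per strain and none per library. Value times length gave whole reads in 100% of regions, against totals of 23817270 reads in ABP1d and 14466014 in WT. The reads in the comparison windows added up to 99.6% of the ABP1d total and 99.7% of the WT total, with a repeat's reads entered at every copy. The totals are thus close to sums of reads over regions; what the authors counted in them is not given in the sources used here, and the sequencing depth of each library is unknown. With pooled values no difference could be set against the spread between replicates, and every interval below is an exact 95% binomial interval on reads that covers counting error only.

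The gene that the annotation names as the CENP-B homolog Abp1 is cbp1 (chromosome II, 3510427 to 3512370). No listed region or window overlapped it, so these small RNA data hold no check of the deletion. Its paralogs cbh1 (chromosome I, 4458920 to 4460878) and cbh2 (chromosome II, 4180737 to 4182438) were also without a region in any list.

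The first comparison asked where each strain carried its most abundant small RNAs. The ABP1d list held 309 regions and the WT list 190, and at the limits of the deposited lists all 190 WT regions overlapped an ABP1d region by at least 1 base. In the other direction, 212 of the 309 ABP1d regions (68.6%) overlapped a WT region and 97 did not. The ABP1d regions covered 68958 bases and the WT regions 58569, of which 51490 were shared. Of the 97 regions found in the ABP1d list alone, 45 lay on tRNA genes and 49 held a run of at least 15 A or 15 T bases. The longest regions of this kind were at 11556 to 11700 and 11382 to 11521 of the mating-type contig, with 3084 and 2001 RPKM in ABP1d. Another 7 of the 10 longest were on tRNA genes, among them a tRNA-Gly gene on chromosome II (180970 to 181076, 11061 RPKM) and a tRNA-Tyr gene on the same chromosome (1598512 to 1598595, 12700 RPKM). The remaining one, at 814836 to 814941 of chromosome III with 10018 RPKM, had no annotated feature. The lists had different lower limits, since the least abundant region had 222 RPM (reads scaled to the strain's total) in ABP1d and 544 in WT. At the common limit of 544 RPM, 209 ABP1d regions remained against the 190 of WT, and 14 ABP1d regions and 16 WT regions did not overlap the other list. The 97 against 0 regions in one list only therefore depend on the lower limit of the ABP1d list.

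The classes of these regions showed what the abundant small RNAs were. tRNA genes held 45 ABP1d regions (14.6%, 95% interval 10.8 to 19.0) and no WT region. The ABP1d regions touched 48 of the 171 nuclear tRNA genes. Both lists held 34 regions on 5S rRNA genes, which were 11.0% of the ABP1d list and 17.9% of the WT list. The repeats of the large rRNA genes on chromosome III held 22 ABP1d and 19 WT regions. Centromeres held 42 ABP1d regions and 18 WT regions, and with 39470 and 43506 bases they were 57.2% and 74.3% of the covered sequence. Neither list held a region on a Tf2 element. At the common limit, ABP1d kept 13 tRNA regions and WT still had none. Regions with an A/T run were 169 of the ABP1d list (54.7%) and 120 of the WT list (63.2%), and they included all 36 ABP1d and all 24 WT regions in the protein-coding class.

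The lists were set against 10000 random placements of regions of the same lengths on the same chromosomes (one-sided, Benjamini-Hochberg over classes and lists). ABP1d regions fell on tRNA genes 35.5 times as often as placed ones, on 5S genes 94.9 times, on the rRNA repeats 16.9 times and on centromeres 11.4 times. Each of these had a permutation p = 0.0001 from the random placements, the smallest that they can give, and adjusted p = 0.0002. WT regions gave 126 times for 5S genes, 23.2 times for the rRNA repeats and 6.87 times for centromeres, each with adjusted permutation p = 0.0002. The windows that differed between strains fell on Tf2 elements 56.3 times as often as placed ones, on tRNA genes 26.7 times, on other long terminal repeats (LTRs) 22.8 times and on snoRNA genes 11.0 times, again with adjusted permutation p = 0.0002. Protein-coding genes were below random placement in all 3 lists, at 0.160 times in ABP1d, 0.172 in WT and 0.616 in the comparison. Regions are not replicates, so these tests describe the lists and not the strains.

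The second comparison, which answers the question of the series most directly, asked which small RNAs differed between ABP1d and WT. The authors' deposited table listed 4012 windows, 3324 of them higher in ABP1d (82.9%) and 688 lower. Tf2 elements, other LTRs and tRNA genes were higher in every listed window. Windows over 28S rRNA and most rRNA spacer windows were higher, and the main 18S rRNA window was lower. With snRNA windows centred the tRNA median fell below 0, as did 157 LTR and 230 Tf2 windows with 0 reads set to 3. A ratio against 0 WT reads is a lower bound, so such a window is not shown to be lower. In centromeric repeats the windows of at least 1000 bases were higher, although not under every scaling, and most shorter windows were lower. WT was listed at 0 in 1713 windows and ABP1d in 75. Windows with the same reads and length made up much of the table, as copies of a repeat often have them. Counted once, they left 1159 higher and 435 lower (72.7% higher). Sequence was not compared, so unrelated windows of few reads also fell together, as some on Tf2-1 and in the rRNA repeats did. Copies that differ by a read or a base still count apart, and 36 of the 37 5S windows stayed. With 0 reads set to 3, centring on the snRNA windows (a shift of -1.96 on the log2 scale) left 2181 windows higher and 1831 lower (54.4% higher). In that scaling 45.8% were higher with equal windows counted once. That shift is the median of 19 windows; by reads, with equal windows counted once, the snRNA class had a ratio of 1.56 (1.46 to 1.66). Centring on the 5S rRNA windows, a shift of -1.25, gave 2856 and 1156 (71.2% higher) with the same floor for 0 reads. No listed window had a deposited p above 0.0494, so windows without a difference are absent from the medians used for centring. These medians are therefore not known to be a stable reference, and the centred values show only how far the directions depend on scaling.

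**Figure D1:**
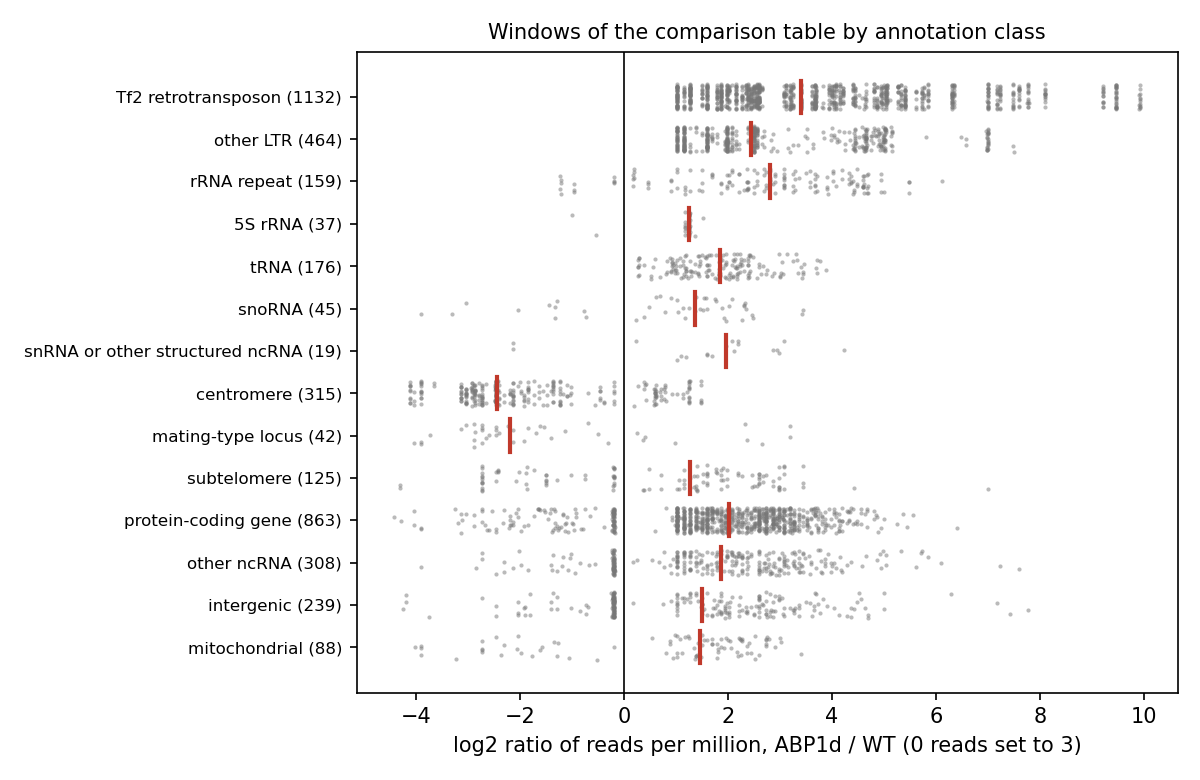
Log2 ratio of RPM (ABP1d over WT, x axis) for each of the 4012 windows of the comparison, by annotation class (y axis, number of windows in parentheses); grey points are windows, with 0 reads set to 3, and red bars are class medians. Every Tf2, other LTR and tRNA window lies above 0, while the centromere median is -2.43. Centred on the snRNA windows, the tRNA median is -0.12. With this floor 157 LTR and 230 Tf2 windows then lie below 0, but a ratio against 0 WT reads is a lower bound.

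Tf2, the LTR retrotransposon family with full-length copies in this genome, gave the highest ratios. All 1132 windows on the 13 elements were higher in ABP1d, with a median log2 ratio of 3.40. A Tf2 element carried 877 to 910 RPM in ABP1d and 3.11 to 3.53 in WT. The ratio per element ran from 251 (Tf2-10, 95% interval 191 to 337) to 282 (Tf2-11, 211 to 387), and the windows covered 50.8% to 54.2% of an element. Elements share almost all of this sequence, so a read was entered at each copy it matched and the 13 ratios are not independent. On Tf2-1 (chromosome I, 1465332 to 1470247), WT was listed at 0 in 73 of 90 windows. The 10 highest ratios of the table were 1 window repeated in 10 elements, at 1467966 to 1468015 in Tf2-1, with 4034 RPKM in ABP1d and 0 in WT. Its 4804 reads against 0 put ABP1d at least 973-fold higher against the floor of 3 reads, with an exact 95% lower limit of 791. Its p-value was 0 in the authors' deposited table. With equal windows counted once, Tf2 windows held 39386 reads in ABP1d and 148 in WT, a ratio of 162 (138 to 191). Variant copies stay in that count, and different positions with equal reads and length fall together, so it is no estimate for 1 element. The ratios above are per element, with reads that match both of its LTRs entered at each. Split by part, equal windows counted once put 72.5% of WT reads on LTRs, against 60.8% on Tf2-1 alone. On Tf2-1 alone, internal windows had 19970 reads against 20, a ratio of 606 (393 to 993). Windows on its LTRs had 1531 against 31, a ratio of 29.9965 (21.0 to 44.3). Several windows recur at both LTRs with the same reads, such as 212 against 1, so those reads were entered at each. This raises the LTR share on Tf2-1 and makes the interval of its LTR ratio narrower than counting error. The Tf2 median stayed above 0 under each of the 5 other scalings tried. With 0 reads set to 3, 1066 of the windows were higher with 5S windows centred and 902 with snRNA windows centred. On Tf2-1, each window that fell below 0 in these scalings had 0 reads in WT, so its ratio is a lower bound and it is not shown to be lower.

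**Figure D2:**
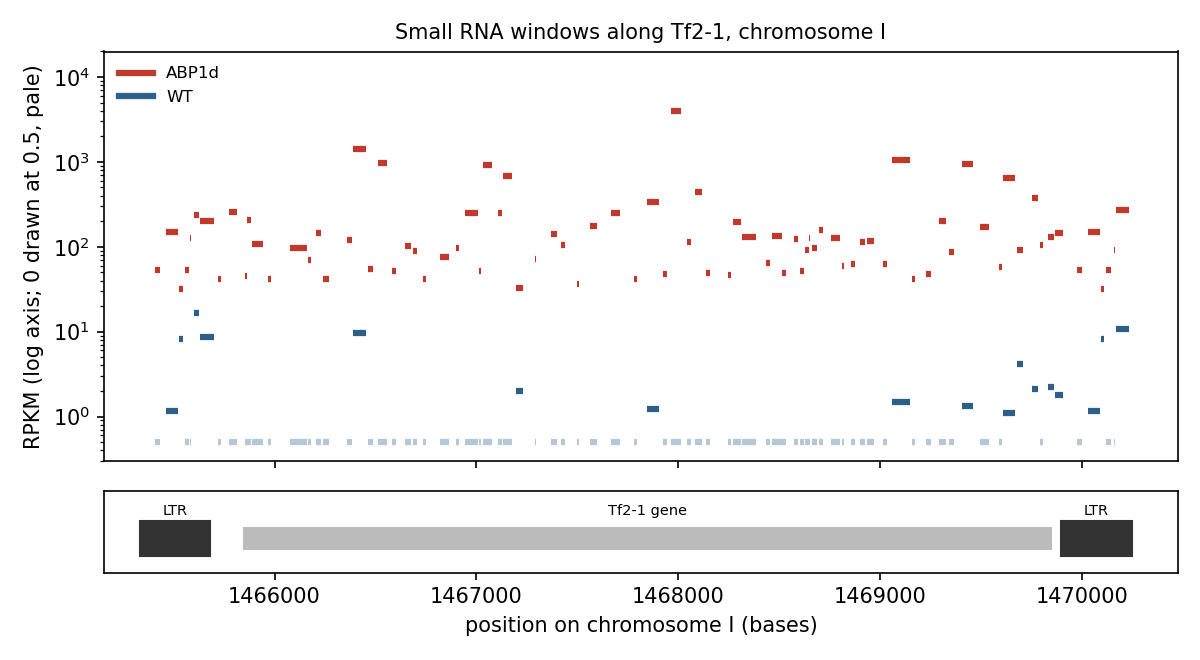
RPKM (log y axis) of each comparison window along Tf2-1 on chromosome I (x axis, bases), red for ABP1d and blue for WT; windows at 0 are drawn pale at 0.5, and boxes below show the LTRs and the gene. ABP1d has reads in all 90 windows and WT is at 0 in 73 of them.

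Other LTRs, which are mostly solitary remnants of such elements, were higher in all 464 windows, with a median log2 ratio of 2.45. Counted once, 107 distinct LTR windows held 622 RPM in ABP1d and 20.1 in WT, a ratio of 30.9 (27.5 to 34.8). The LTR median stayed above 0 under the 5 other scalings. With 0 reads set to 3, 85 of the windows fell below 0 with 5S windows centred and 157 with snRNA windows centred. Where WT had 0 reads the ratio is a lower bound, and such a window is not shown to be lower.

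The rRNA repeats on chromosome III changed in opposite directions within 1 repeat. A window over the 28S gene (5805 to 9559; gene at 6057 to 9541) had 13872.5 RPKM in ABP1d and 562.5 in WT, a 24.7-fold higher value (24.4 to 24.9). The window over 18S (10662 to 12303; gene at 10419 to 12260) had 32026 RPKM in ABP1d and 74442 in WT, a 2.32-fold higher value in WT (2.32 to 2.33). Over 5.8S (9816 to 10009), ABP1d had 93465 RPKM and WT 81952, a ratio of 1.14 that lay below 1 under 4 of the 5 other scalings. The directions of the main 28S and 18S windows held under all 5. Of the 11 windows on 18S, 6 were higher and 5 lower, or 3 and 4 with equal windows counted once, and one at 10411 to 10618 had 2553 reads in ABP1d against 1130, a ratio of 1.37 (1.28 to 1.47). Summed over the rRNA repeat with equal windows counted once, reads gave a ratio of 0.669 (0.668 to 0.670). Copies that differ by a few reads or bases stay in this sum, which held 5000298 ABP1d reads on 18S and 2480642 on 28S. The main 18S and 28S windows alone held 1252469 and 1240668, so 18S weighs more and the interval counts reads repeatedly. Within the genes of 1 repeat, the reads were 12.3% of the ABP1d total and 14.0% of the WT total. Outside the genes and without A/T runs, 135 of 138 spacer windows were higher, 46 of them with WT at 0. Such a window at 3792 to 3840 had 221 reads in ABP1d against 0, at least 44.7-fold higher. The p-values of the 28S and 18S windows were 0 in the authors' deposited table.

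**Figure D3:**
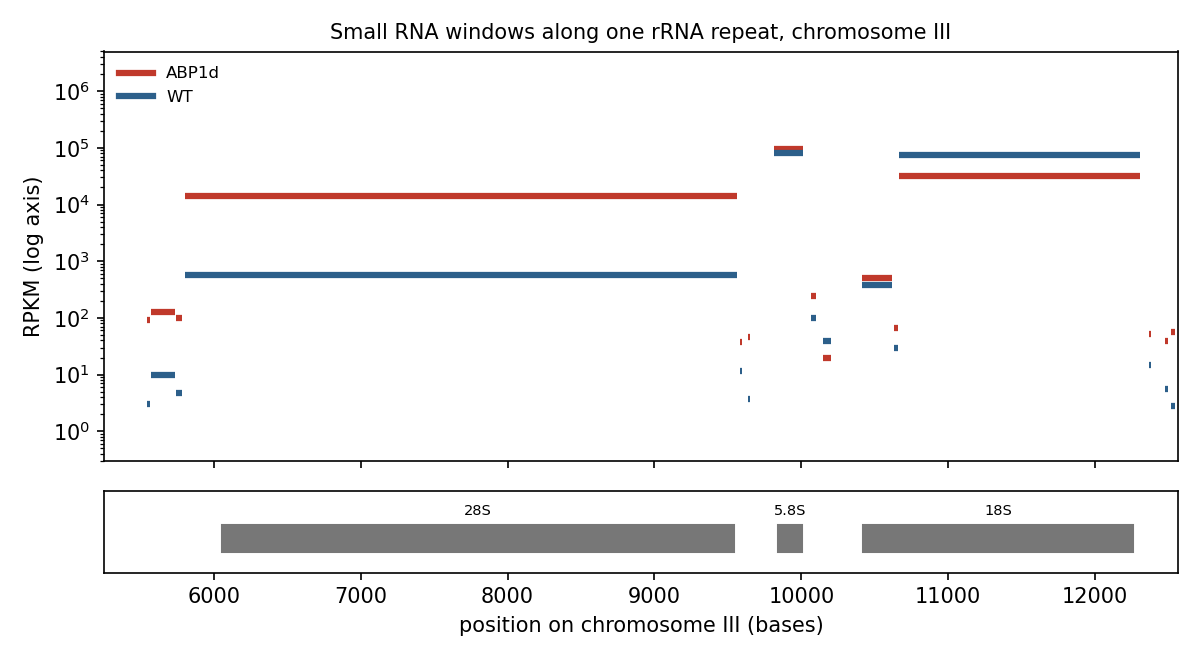
RPKM (log y axis) of each comparison window along 1 rRNA repeat on chromosome III (x axis, bases), red for ABP1d and blue for WT, with the rRNA genes as boxes below. The 28S window is 24.7-fold higher in ABP1d, and the main 18S window is 2.32-fold higher in WT.

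Among the other stable RNAs, 35 of 37 windows on 5S rRNA genes were higher, with a median log2 ratio of 1.25 that became negative on centring to the snRNA windows. The copies carried nearly the same reads; one on chromosome II (2261359 to 2261490) had 60303 RPKM in ABP1d and 26601 in WT. All 176 tRNA windows, on 166 of the 171 nuclear tRNA genes, were higher, with a median log2 ratio of 1.84 that also fell below 0 only when snRNA windows were centred. The tRNA window with the most reads lay in a tRNA-Ala gene (chromosome I, 4796971 to 4797003), at 48182 RPKM in ABP1d and 3274 in WT, 14.7-fold higher (14.0 to 15.5). snoRNA genes, whose RNAs guide rRNA modification, had 35 higher and 10 lower windows, which became 24 and 21 with 5S windows centred and 12 and 33 with snRNA windows centred. Most snoRNA reads came from snoZ15 (chromosome II, 1756157 to 1756215; 39790 against 16635 RPKM), and snoR69b (chromosome I, 4154968 to 4155012) was 1.70-fold higher in WT (1.51 to 1.91).

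Centromeres gave 56 higher and 259 lower windows, and the direction followed the length of the window. The annotation used has no dg or dh feature, so these outer repeats are described by the centromeric transcripts it lists. All 16 windows of at least 1000 bases were higher in ABP1d, by 1.21-fold to 1.91-fold, and they held 92.6% of the centromeric window reads in ABP1d and 88.0% in WT. They included 3761484 to 3764035 at centromere I (1546 against 891 RPKM), 1641053 to 1643042 at centromere II (1705 against 893) and 1114641 to 1118279 at centromere III (1582 against 970). Summed, these long windows were 1.57-fold higher (1.57 to 1.58), and the ratio fell below 1 under 3 of the 5 other scalings. The sum held 1473736 ABP1d reads, more than the 1288437 of all centromeric windows with equal ones counted once. Some long windows thus carry the same reads, and the interval is narrower than counting error. By reads rather than length, and with A/T runs kept, 18 of the 41 centromeric windows with at least 1000 reads were higher and 23 lower. All 6 centromeric windows with an A/T run, whatever their reads, were lower. Of the 262 windows under 100 bases without an A/T run, 231 were lower, with a median of 23 reads in both strains together. Summed in the same way, these short windows had a ratio of 0.783 (0.761 to 0.805). Windows of intermediate length went both ways, and one at 3753495 to 3753969, at the edge of centromere I, had 71.0 RPKM in ABP1d and 167 in WT, a 2.36-fold higher value in WT (2.15 to 2.58).

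Heterochromatin elsewhere showed a similar mixture. On the contig of the mating-type region, whose cenH part resembles the centromeric repeats, 4 windows were higher and 33 lower. The 4 higher ones included 11953 to 13090 (1016 against 766 RPKM) and 11549 to 11712 (2727 against 1387), while 10655 to 10859, which also had over 1000 reads, was lower (292 against 413). All windows of the contig together were 1.28-fold higher (1.26 to 1.30), which turned lower under 3 of the 5 other scalings. At the subtelomeric helicase genes, 31 of 33 windows on tlh1 and 29 of 31 on tlh2 were higher, with summed ratios of 2.05 (1.92 to 2.19) and 2.04 (1.92 to 2.18). These genes held nearly the same reads (3976 against 1178 on tlh1, 3959 against 1176 on tlh2), so the ratios should not be taken as independent. Both ratios fell below 1 on centring to the 5S or the snRNA windows.

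The 10 lowest ratios of the table were all on windows with few reads, 3 of them centromeric and 2 subtelomeric. The best covered lay in tdh1, a glycolytic dehydrogenase gene (chromosome II, 2808940 to 2808969), with 7 reads in ABP1d and 83 in WT, 19.5-fold higher in WT (9.07 to 50.1), and p = 0 in the authors' deposited table. The lowest, in rga3 (chromosome I, 5123337 to 5123346), had 1 read against 13, with an interval of 3.21 to 910 for its ratio of 21.4 in favour of WT.

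Protein-coding genes outside repeats were mostly higher where a window was listed: of 705 such genes, 91.6% had only higher windows once A/T runs were left out. The median window of the class stayed above 0 under the 5 other scalings, by 0.06 with snRNA windows centred. Abundant mRNAs departed from this. Of 11 genes of the glycolysis and abundant mRNA list with a window, 5 had only higher windows and 6 had a lower one, with a median log2 ratio of -1.36 over the list, against 92.4% with only higher windows among other genes (Fisher's exact test, two-sided, adjusted p = 0.00036). The higher genes included adh1, an alcohol dehydrogenase gene (98 against 3 reads, ratio 19.8, 6.59 to 97.9), and the elongation factor genes tef101, tef102 and tef103 with ratios of 7.98, 7.41 and 7.24. The genes with a lower window, named after their values were seen, were tdh1, eno101, pgk1, fba1, pyk1 and the proton pump gene pma1 (194 against 302 reads, ratio 0.390, 0.324 to 0.469). Ribosomal protein genes, whose median log2 ratio was 2.09, had a lower window more often than other genes, with 46 of 61 having only higher windows against 93.0% of the others (Fisher's exact test, adjusted p = 0.00036). Neither test took account of windows per gene, and a gene with more windows has more chances of a lower one. Among the abundant mRNA genes, adh1 had 3 windows and tef101, tef102 and tef103 had 6, 7 and 8. The largest ratios of the ribosomal protein genes were in rps21 (49 reads against 1, ratio 29.8, 5.10 to 1199) and rpl35A01 (39 against 1, ratio 23.7, 4.01 to 959). Next came rpl901 (59 against 2, ratio 17.9) and rps2502 (29 against 1, ratio 17.6).

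The other gene lists had few windows. No gene of the RNAi machinery list and none of the phosphate and ncRNA-regulated list had a window. In the heterochromatin list, swi6, the HP1 homolog, had 50 reads against 10 (ratio 3.04, 1.52 to 6.72) and chp2 had 12 against 0, at least 2.43-fold higher. Of 9 snRNA and stable ncRNA genes with a window, 8 had only higher ones, led by the spliceosomal RNA gene snu2 (298 against 31 reads, ratio 5.84, 4.03 to 8.75) and by mrp1, snu1 and snu3 with ratios of 4.56, 3.49 and 2.88. In the histone list 5 genes had a window, among them hht2 with 17 against 3 reads (ratio 3.44, 0.996 to 18.3), hht1 with 39 against 8 (2.96, 1.36 to 7.34), htb1 with 13 against 0 and hhf2 with 10 against 0. In the stress list, hsp9 had 28 reads against 2 (ratio 8.50, 2.14 to 73.7), hsp104 had 10 against 1 (6.07, 0.864 to 264), tps1 had 37 against 5 (4.49, 1.76 to 14.7) and ish1 had 18 against 0. The intervals of hht2 and hsp104 include 1. The meiotic gene mei3 had 15 reads against 0 and wtf9, of the wtf spore killer family, 29 against 0. The snRNA list did not pass against other genes (Fisher's exact test, adjusted p = 1); the heterochromatin, histone, stress, meiotic and wtf lists had 1 to 5 genes with a window, too few for the test to tell, and the RNAi and phosphate lists could not be tested. Directions of these genes under other scalings were not examined gene by gene.

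The direction of windows by class was compared with that of all other windows by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 14 classes. By Fisher's exact test, Tf2 windows were higher in 100% against 76.1% of other windows (adjusted p = 1.99e-110), other LTRs in 100% against 80.6% (adjusted p = 1.98e-40) and tRNA windows in 100% against 82.1% (adjusted p = 7.70e-15). rRNA repeat windows were higher in 92.5% against 82.5% (adjusted p = 0.00083), and 5S windows in 94.6% against 82.7%, which did not pass (adjusted p = 0.088) but did with windows merged (0.0090) or equal ones counted once (0.0033). With 5S windows centred the tRNA difference was 1.61 percentage points (Fisher's exact test, adjusted p = 0.72), and with snRNA windows centred it turned to -11.7 (0.0032). The 5S difference turned to -22.7 and -54.9 under these scalings, and the protein-coding one to -3.12 with snRNA windows centred. In the same exact test, centromeric windows were higher in 17.8% against 88.4% (adjusted p = 9.12e-159), mating-type windows in 21.4% against 83.5% (adjusted p = 9.14e-18) and subtelomeric ones in 60.8% against 83.6% (adjusted p = 6.72e-09). Protein-coding windows differed from others in Fisher's exact test by 3.25 percentage points (adjusted p = 0.032), mitochondrial windows by -10.4 (adjusted p = 0.021), snoRNA windows by -5.13 (adjusted p = 0.35) and snRNA windows by 6.65 (adjusted p = 0.76). Other ncRNA and intergenic windows differed in the exact test by -8.86 (adjusted p = 0.00026) and -23.1 (adjusted p = 3.10e-16), and without A/T runs these differences turned to 5.86 and 0.390. The tests treat copies of a repeat as separate windows. With windows within 100 bases merged, the Tf2 and mating-type differences were 21.0 and -12.5 points and no longer passed Fisher's exact test (adjusted p = 0.080 and 0.52). The rRNA repeat difference turned to -6.83 on merging. Counting equal windows once gave 28.9 for Tf2 (Fisher's exact test, adjusted p = 1.33e-12) and -51.7 for the mating-type locus (1.01e-06). The mitochondrial difference did not pass on merging (Fisher's exact test, adjusted p = 0.76) or with equal windows counted once (0.68), nor the rRNA difference with equal windows counted once (0.098). The protein-coding difference did not pass with equal windows counted once (Fisher's exact test, adjusted p = 0.056) or with the class taken from the most bases (0.057).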

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

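The common limit, the removal of A/T runs, the counting of equal windows once, the limit of 100 reads and all scalings were chosen after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible, because each strain has a single pooled value. Alternatives that need counts per library (another normalization with its test, a filter on low counts, a replicate block, leaving out each library) were not run for the same reason; alternatives on strand were not run because the files give none. Pooled reads limit precision to counting error, and windows of about 10 reads have wide intervals.

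Counts of regions and of overlapping regions stayed within 1.5 times of the reported ones when regions were merged within 100 bases, when overlap had to reach 50% of both regions, and at the common limit. Regions in one list only were less stable: at the common limit they were 14 in ABP1d and 16 in WT, and with overlap of 50% of both regions 16 in WT. Keeping the more abundant part of each list left 155 ABP1d and 95 WT regions, with 95 and 95 overlapping and 60 in ABP1d only. Without A/T runs 140 ABP1d and 70 WT regions were left, with 92 and 70 overlapping and 48 in ABP1d only. Fewer regions follow from how both alternatives are made.

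Class shares of the lists kept 16 values within their intervals and moved 16. As covered bases, the ABP1d shares were 4.89% for tRNA, 5.63% for 5S, 24.6% for the rRNA repeats and 57.2% for centromeres, and the WT shares 7.34% for 5S and 74.3% for centromeres. At the common limit, ABP1d shares were 6.22% for tRNA, 16.3% for 5S and 18.7% for centromeres. Without A/T runs they were 32.1%, 24.3% and 27.1%, with 11.4% for the rRNA repeats, against WT shares of 48.6% for 5S, 22.9% for the rRNA repeats and 24.3% for centromeres.

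The count of higher windows was 1159 with equal windows counted once, 990 with at least 100 reads and 2181 with snRNA windows centred. The count of lower windows was 432 with an absolute log2 ratio at least 1 above the smallest, 435 with equal windows counted once, 287 with at least 100 reads, 1156 with 5S windows centred and 1831 with snRNA windows centred. The other 10 counts stayed within 1.5 times.

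Of the class differences in direction, 110 of the values under alternatives kept their sign and their side of 0.05. Centromere, other LTR and subtelomere differences did so under all 10 alternatives, the 5 scalings included. By the same Fisher's exact test, merging gave 21.0 points for Tf2 (adjusted p = 0.080), -6.83 for the rRNA repeats (0.50), 18.4 for 5S (0.0090), 4.75 for snoRNA (0.76), -12.5 for the mating-type locus (0.52) and -2.45 for mitochondrial windows (0.76). Merging leaves fewer windows to test; the cause of the changed signs was not tested. Fisher's exact test with equal windows counted once gave 12.0 for the rRNA repeats (adjusted p = 0.098), 22.2 for 5S (0.0033), 5.48 for snoRNA (0.56), 5.02 for protein-coding genes (0.056) and -2.22 for mitochondrial windows (0.68). With the class taken from the most bases, protein-coding genes gave 2.98 (Fisher's exact, adjusted p = 0.057). In the part of the windows with the larger absolute log2 ratio, other ncRNA gave 8.66 (Fisher's exact, adjusted p = 0.0051) and intergenic 3.95 (0.42), and 5S gave no value. Without A/T runs, other ncRNA gave 5.86 (Fisher's exact, adjusted p = 0.0091) and intergenic 0.390 (1). Fisher's exact test without rRNA repeat reads gave 5.76 for the rRNA repeats (adjusted p = 0.083) and 13.5 for 5S (0.043). With A/T-run windows centred, other ncRNA gave -1.22 (Fisher's exact, adjusted p = 0.60). With 5S windows centred, 5S gave -22.7 (Fisher's exact, adjusted p = 0.0081), tRNA 1.61 (0.72), snoRNA -18.1 (0.015), snRNA -2.78 (0.80) and protein-coding genes 3.49 (0.054). With snRNA windows centred, 5S gave -54.9 (Fisher's exact, adjusted p = 9.49e-13), tRNA -11.7 (0.0032), snoRNA -28.0 (0.00031), snRNA -7.03 (0.65) and protein-coding genes -3.12 (0.11). Adjusted p over the alternatives ran from 3.76e-122 to 0.080 for Tf2, 9.32e-07 to 0.50 for the rRNA repeats, 9.49e-13 to 0.36 for 5S, 1.94e-22 to 0.72 for tRNA, 0.00031 to 0.76 for snoRNA, 0.49 to 1 for snRNA, 2.47e-22 to 0.52 for the mating-type locus, 3.48e-07 to 0.11 for protein-coding genes, 0.00031 to 0.60 for other ncRNA, 3.10e-16 to 1 for intergenic and 0.000080 to 0.76 for mitochondrial windows.

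Random placement kept its direction and its side of 0.05 in 79 values. Without A/T runs, the subtelomere ratio went to 0 in the ABP1d list and 0 in the WT list, since nearly all subtelomeric regions there hold such a run.

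Scaling without rRNA repeat reads shifted all log2 ratios by -0.66, with rRNA, 5S and A/T-run reads at 1 copy by -0.33, and with A/T-run windows centred by 0.20. Of the class medians and loci, 40 values stayed within their range, 47 moved with the same sign, 2 became 0 because their own class was centred, and 21 changed sign, which follows from the shift. With snRNA windows centred, medians were -0.71 for 5S, -0.12 for tRNA, -0.58 for snoRNA, -0.68 for subtelomere, -0.093 for other ncRNA, -0.46 for intergenic and -0.50 for mitochondrial windows. 5.8S gave -0.47 without rRNA repeat reads, -0.14 with reads at 1 copy, -1.06 with 5S windows centred and -1.77 with snRNA windows centred. In the order without rRNA repeat reads, 5S centred and snRNA centred, long centromeric windows gave -0.0099, -0.60 and -1.31 and the mating-type contig -0.30, -0.89 and -1.60. With 5S and snRNA windows centred, tlh1 gave -0.22 and -0.92, and tlh2 -0.22 and -0.93.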

Other observations

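The tests of independent change at A/T runs, of LTR windows without Tf2 sequence and of the balance of directions were chosen after the results were seen; the others were written before.

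On the mitochondrial contig, 64 windows were higher in ABP1d and 24 lower, with a median log2 ratio of 1.45 that was -0.50 with snRNA windows centred. The most abundant higher windows were at 17534 to 17568 of the contig (2509 against 289 reads, ratio 5.27, 4.67 to 5.98) and at 18058 to 18083 (1967 against 149 reads, ratio 8.02, 6.79 to 9.54). These positions were chosen after their values were seen.

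Regions with an A/T run shared nearly one ratio, with a median log2 ratio of -0.20 over 220 windows and 217 of them lower in ABP1d. The quartiles were -0.205 and -0.196 (interquartile range 0.00878), with medians of 11327 reads in ABP1d and 7935.5 in WT. This range describes the pattern and is no separate test. Changes at each locus on its own would not give 1 shared ratio, so for these windows as a set the values argue against them. Of the 145 runs of at least 20 A or T bases in the genome, 100% lay in a region of the ABP1d list. Reads of A or T alone, placed at every such run, may therefore account for these regions. Whether such reads differ between the strains for a biological reason was not tested.

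Other LTRs were higher in ABP1d in every listed window as scaled to the totals. With snRNA windows centred and 0 reads set to 3, 157 of 464 had a log2 ratio below 0. Of 87 distinct LTR windows of at least 20 bases, 93.1% shared 20 bases with a Tf2 element, against 0 of 307 protein-coding windows. Reads of Tf2 elements placed on solitary LTRs may account for much of this pattern, but the test cannot decide it. Remnants of such elements share their sequence wherever the reads arose. The protein-coding class leaves out windows that touch Tf2 or an LTR, so its 0 is no independent contrast. Among the 6 windows without shared sequence, 100% were higher (771 against 49 reads), and 6 are too few to tell whether solitary LTRs were also higher on their own.

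More windows were higher than lower in ABP1d. With equal windows counted once, 72.7% were higher. This count cannot settle the part of repeat copies, because copies that differ by a read or a base stay in it, as 36 of 37 5S windows did. Unrelated windows with equal reads and length are also joined in it. Of 728 distinct windows with at least 100 reads, 65.2% were higher (95% interval 61.7 to 68.7, which takes such copies as independent). The majority was thus not confined to windows with few reads. Over all windows, equal ones counted once, the share was 69.8%, 71.6%, 79.2% and 61.4% under 4 of the other scalings and 45.8% with snRNA windows centred. These shares follow from the size of each shift and test no explanation. The centred scalings also rest only on windows listed as different between the strains. Whether the scaling sets the balance or small RNA rose more widely in ABP1d stays open, because the library depth is unknown.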
